A study of Mus musculus with 4 samples.

How the data were processed

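The series measured RNA of AML12 mouse hepatocytes infected with shCtrl or shTopors lentivirus, 2 libraries per group. Per the labels' protocols, the medium was changed at 24 hours, cells were collected 5 days after infection, RNA was extracted with TRIzol, and libraries were depleted of ribosomal RNA and strand-specific. The deposited table holds TPM per gene and library, as made by the authors. The submitters' processing notes name HISAT2, HTSeq, DESeq2 and StringTie and the build mm10, as tools the authors used, without versions or roles. The strand setting and the program that wrote the TPM are not given in the sources used here.

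The table had 52633 rows and 52630 gene identifiers. For 3 identifiers on 2 rows the values were summed. Symbols turned into dates by a spreadsheet numbered 27, and 26 were restored through the identifier. Each column was assigned to its sample by its name, and no column was left over. Of the identifiers, 52483 were found in GENCODE M21, whose mm10 coordinates, transcript lengths and GC content were used. TPM summed to 999933, 999914, 999943 and 999925 in shCtrl 1, shCtrl 2, shTopors 1 and shTopors 2. TPM keeps no depth, so the depth is unknown and no counting interval or detection limit was computed. Genes of at least 1 TPM numbered 13581, 13847, 12928 and 13112 in the same order. Small RNAs took 24.2%, 17.9%, 18.5% and 20.2% of TPM. The genes with the highest mean TPM were Rn7sk, Rn7s2, AC157822.1, Rpph1 and Gm26917, all noncoding, and a shift in such genes moves the TPM of all others.

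Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, over 13509 genes with a mean of at least 1 TPM. The contrast was shTopors minus shCtrl with no other term. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of low genes. P-values were adjusted with the Benjamini-Hochberg method and called under 0.05. Gene lists, 42 in all, were tested with limma's camera at a preset correlation of 0.01 when at least 5 members were tested, and adjusted over 36 lists. Camera with an estimated correlation and fry, which tests whether members move on balance in either direction, were run beside it. With an estimated correlation camera rests on the 2 residual degrees of freedom, so it had little power after adjustment over 36 lists. Single-gene p-values of each list were also adjusted over the list alone. Lists of stellate cell, endothelial, leukocyte, germline, receptor and HOX genes had 3, 4, 1, 1, 3 and 4 tested members and were not tested.

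Neighbouring genes were compared by the correlation of their log2 changes against 10000 shuffles. The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes Topors, then genes past the threshold with both knockdown libraries beyond both controls, a higher group mean of at least 5 TPM and no provisional symbol, up to 12 per direction. Where fewer passed, the genes with the smallest p under the same conditions filled up to 6 per direction, said not to pass. Each list gives up to 4 members past the threshold, or else the member with the smallest p, and the 5 genes with the highest mean TPM describe the libraries. The text gives only some of these members, and 1 result under this rule is not reported here.

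Alternatives were other pseudocounts (0.1 and 5), filters, scalings between libraries, variance models, a replicate block, and each library left out in turn. Added after seeing the data were neighbours under these settings, genes and lists after a trend on transcript length and GC was removed, counts at an unadjusted p, and a sum of other cell types' markers restricted to those with a control mean under 1 TPM. The steps were tested on simulated data for the contrast of shTopors with shCtrl, with 200 changed genes of 13509 in 10 simulations. Recovery was 2.8% at a log2 change of 1, 73.2% at 2, 95% at 3 and 99.2% at 4, with 6.4 false calls among 141.5 calls on average. The changed genes were drawn only from genes with higher control means, so this recovery does not cover low genes. The adjusted threshold also becomes stricter when fewer genes pass. Far fewer passed in the data than in these simulations, so recovery in the data would be lower than these shares. A planted list of 30 genes shifted by 0.8 was found at an unadjusted camera p under 0.05 in 10 of 10 simulations. Genes were simulated independently and with equal spread in both groups. Neither the preset nor the estimated correlation was therefore tested on lists of correlated members, such as G2/M genes (estimated correlation 0.936). Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.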

Results

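AML12 is a non-tumour mouse hepatocyte line established from liver cells of mice that carry a human TGF-alpha transgene. AML12 cells were infected with lentivirus carrying a control short hairpin RNA (shCtrl) or a hairpin against Topors (shTopors), whose product is an E3 ligase for both ubiquitin and SUMO. Cells were given 200 µl of concentrated virus and were collected 5 days later. Total RNA was depleted of ribosomal RNA and sequenced as strand-specific libraries, 2 per group. Transcript levels are TPM, a length- and library-scaled abundance, and the number of reads behind each value is unknown because TPM keeps no depth. The tested set held 13509 genes with a mean of at least 1 TPM over the 4 libraries. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

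The comparison of shTopors with shCtrl asks how a lower Topors level alters transcript levels in hepatocytes, in a study whose title concerns higher-order chromatin organization. Topors (ENSMUSG00000036822, mm10 chromosome 4, 40259601 to 40269850, minus strand) was listed at 21.9 and 29.2 TPM in shCtrl and at 4.31 and 4.65 TPM in shTopors. The group means were 25.6 ± 5.16 and 4.48 ± 0.242 TPM (SD, n = 2), which is 5.71-fold lower in the knockdown. Both knockdown libraries therefore went with their labels. In limma's fit across all genes the log2 difference in Topors transcript level was -2.27 (SE 0.288), with an adjusted p = 0.0823 that did not pass the threshold of 0.05. Without shTopors 1 or shTopors 2 the adjusted p was 3.39e-06 or 1.895e-07, and without shCtrl 1 or shCtrl 2 it was 0.306 or 0.872, with the lone library assumed to vary like the other group. Topors overlaps the antisense gene Toporsos, and the strand setting of the counting is not given in the sources used here.

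In the knockdown, 4 genes fell and 1 rose past an adjusted p of 0.05 in limma's test. Spp2, a secreted phosphoprotein made in liver, fell from 186 ± 56.5 to 4.63 ± 0.0561 TPM (SD, n = 2). Its log2 change was -5.02 (SE 0.297, adjusted p = 0.00688). Xdh, which encodes xanthine dehydrogenase of purine breakdown, fell from 233 ± 47.9 to 34.3 ± 0.442 TPM, a log2 change of -2.71 (SE 0.252). Alpl, the tissue-nonspecific alkaline phosphatase gene, fell from 15.8 ± 0.928 to 0.755 ± 0.273 TPM, a log2 change of -3.26 (SE 0.291). The small nucleolar RNA Snord60 rose from 0.141 ± 0.0600 to 9.51 ± 0.0978 TPM, a log2 change of 3.20 (SE 0.281). The mitochondrial gene mt-Atp6 fell from 7.80 ± 1.09 to 0.0228 ± 0.00996 TPM, a log2 change of -3.10 (SE 0.287). Xdh, Alpl, Snord60 and mt-Atp6 shared an adjusted p = 0.0310 in limma's test. Of the 5, only Spp2 kept its call without shCtrl 1, after median-of-ratios scaling, after quantile normalization and after a trend on transcript length and GC was removed. With a filter at a mean of 5 TPM, and when rescaled without small RNAs, mitochondrial genes and the most abundant genes, Spp2 passed and Xdh and Alpl did not, while Snord60 and mt-Atp6 were left out of the test. With no filter on low values or without shCtrl 2, none of the 5 did, and with no mean-variance trend Xdh did not (adjusted p = 0.0694). All 5 genes lay on the same side of both control libraries in both knockdown libraries. A call with 2 libraries per group nearly requires this, and 49.8% of tested genes showed it, so it is not separate support.

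In mm10 coordinates, Spp2 spans 88406961 to 88426438 on the plus strand of chromosome 1, and Alpl spans 137741733 to 137796384 on the minus strand of chromosome 4. Xdh spans 73883895 to 73950196 on the minus strand of chromosome 17. Snord60 lies at 24528476 to 24528553 on the plus strand of chromosome 17, within Rab26os on the same strand, so its reads and those of Rab26os are hard to tell apart. The mt-Atp6 gene, at 7927 to 8607 of the mitochondrial genome, overlaps mt-Atp8 and mt-Co3 on its strand. Its value is uncertain for that reason. For comparison, mt-Co1, chosen after its values were seen, was listed at 5668 and 6845 TPM in shCtrl.

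**Figure D1:**
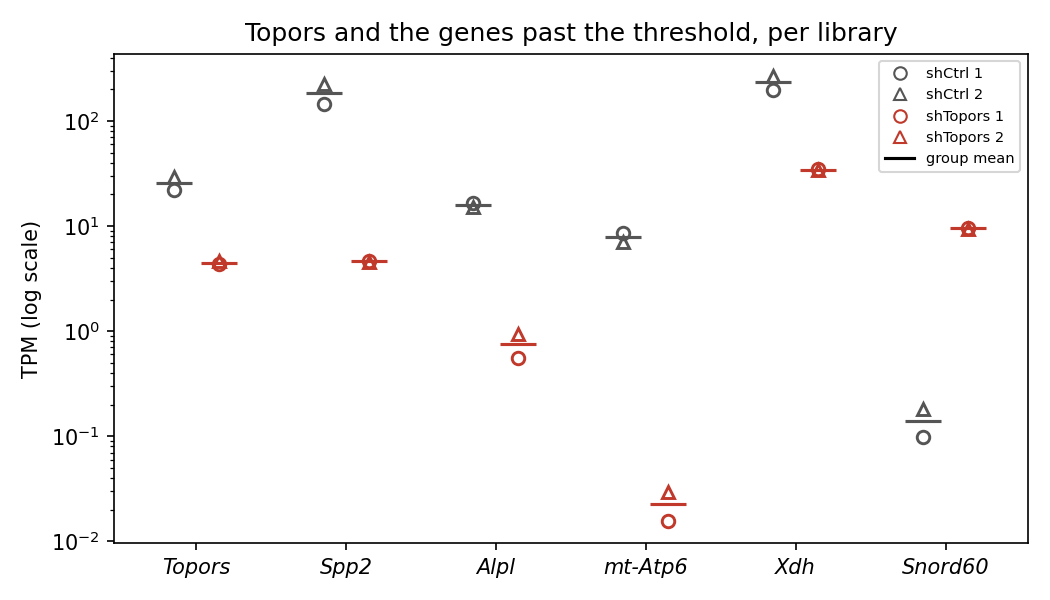
Levels of Topors and of the 5 genes past an adjusted p of 0.05 in each library, in TPM on a log axis. Grey marks are shCtrl, red marks are shTopors, circles are replicate 1, triangles are replicate 2 and bars are group means. Spp2 stands at 146 and 226 TPM in shCtrl against 4.67 and 4.59 TPM in shTopors.

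The knockdown libraries differed more from each other than the controls did. The SD of the log2 difference over tested genes was 0.688 between the knockdown libraries and 0.429 between the controls. At least 2-fold apart were 1455 genes in the knockdown pair and 321 in the control pair. Without shTopors 1 the counts were 246 higher and 901 lower, and without shTopors 2 they were 687 higher and 1479 lower. Without shCtrl 2 no gene passed in either direction. With all libraries 537 genes were higher and 1447 lower at an unadjusted p under 0.05, against 675 expected by chance. These counts were 133 and 780 without shCtrl 1, 266 and 428 without shCtrl 2, 717 and 2054 without shTopors 1, and 1229 and 2666 without shTopors 2. The share of higher genes was 27.1% with all libraries and from 14.6% to 38.3% with 1 left out, and it was 53.8% after median-of-ratios scaling and 53.7% after quantile normalization. These scalings moved the median log2 change of all genes from -0.183 to -0.016 and -0.006, so gene groups are given below as their median excess over all genes. The groups did not overlap for 49.8% of tested genes, against 33.3% by chance. That share comprised 1970 genes higher and 4751 lower.

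Several genes with large differences did not pass the threshold. Tgfa, an EGF receptor ligand, was at 108 ± 6.58 TPM in shCtrl and 17.6 ± 3.68 TPM in shTopors (SD, n = 2), with an adjusted p = 0.0534 in limma's test. Reads from the TGF-alpha transgene of AML12 were not separated here. Klb, which encodes the FGF21 co-receptor beta-Klotho, was at 39.3 ± 8.88 and 5.06 ± 0.849 TPM, with an adjusted p = 0.0664. Cox5a, a cytochrome c oxidase subunit gene, was at 86.8 ± 24.0 and 340.3 ± 15.2 TPM, and Lgals1, which encodes galectin-1, at 736 ± 73.5 and 1766 ± 387 TPM. Sprr1a was at 0.998 ± 0.381 and 14.8 ± 5.80 TPM. Mcpt8 was at 2.31 ± 1.68 and 38.3 ± 30.8 TPM and Klra4 at 2.22 ± 0.210 and 29.4 ± 23.5 TPM, and both belong to multigene families whose copies can share reads. The adjusted p of Cox5a and Sprr1a was 0.0823, and that of Lgals1, Mcpt8 and Klra4 was 0.130. Tgfa and Klb passed with a robust empirical Bayes fit (adjusted p = 0.0268 and 0.0300), and Tgfa with a pseudocount of 5 (0.0466). With 1 library left out, the log2 change ranged from 1.70 to 2.27 for Cox5a and from 1.02 to 1.47 for Lgals1. It ranged from 2.56 to 3.33 for Sprr1a, from 2.50 to 4.31 for Mcpt8 and from 2.10 to 3.87 for Klra4.

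As sets in limma's camera test, G2/M, histone and G1/S genes were higher in the knockdown. Each of these lists had an adjusted p = 0.769 with an estimated correlation. Of 32 G2/M and mitosis genes, all 32 lay above the median change of all genes and 31 had groups that did not overlap. None passed over all genes tested, and 30 passed adjusted over the list alone. Their median excess over all genes was 1.37 on the log2 scale, and Birc5, the survivin gene, was at 13.0 ± 0.682 TPM in shCtrl and 38.2 ± 15.2 TPM in shTopors (SD, n = 2). Of 67 replication-dependent histone genes, 65 lay above the all-gene median, none passed over all genes and 35 passed adjusted over the list alone, with a median excess of 1.06. Hist1h4k, a histone H4 gene with near-identical copies, was at 233 ± 43.2 and 504 ± 83.0 TPM. The 32 G1/S and replication genes had a median excess of 0.495, and none passed adjusted over the list alone. Mcm10, a replication factor, was at 3.47 ± 0.501 and 9.89 ± 3.83 TPM. The mean of the G1/S list in shTopors 2 lay between those of the controls. Without shTopors 1 the median excess was 0.892 for G2/M genes and 0.212 for G1/S genes, and without shTopors 2 it was 0.766 for G1/S genes. The camera adjusted p was 1.32e-26 for G2/M genes, 2.73e-34 for histones and 8.36e-07 for G1/S genes.

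Cytosolic ribosomal protein genes and cholesterol synthesis genes were also higher as sets in camera, the latter mostly in shTopors 1. Both lists had an adjusted p = 0.769 with an estimated correlation, and no member of either passed over all genes or adjusted over the list alone. Of 78 cytosolic ribosomal protein genes, 76 lay above the all-gene median, with a median excess over all genes of 0.559 and a camera adjusted p = 1.05e-24. After quantile normalization the excess was 0.231 and the adjusted p = 9.07e-06. Rpl8, whose family has many processed copies, was at 2238 ± 41.2 and 3602 ± 277 TPM. Of 25 cholesterol synthesis genes, 24 lay above the all-gene median, with a median excess of 1.43 and a camera adjusted p = 3.14e-11. Mvk, the mevalonate kinase gene, was at 11.4 ± 0.383 and 32.8 ± 19.3 TPM. The list's mean relative to the control mean was 2.15 in shTopors 1 and 0.165 in shTopors 2, where shCtrl 2 stood at 0.171. Its median excess was 0.356 without shTopors 1 and 2.18 without shTopors 2.

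Genes for secreted hepatocyte proteins and for hepatocyte transcription factors were lower as sets in camera, while drug and bile acid metabolism genes did not pass. Both lower lists had an adjusted p = 0.769 with an estimated correlation. Of 25 genes for proteins secreted by hepatocytes, 21 lay below the all-gene median and 6 passed adjusted over the list alone. Their median excess was -0.746, with a camera adjusted p = 0.00021, and the call was lost with no filter on low values (adjusted p = 0.0747, excess -0.477). The excess was -1.16 without shCtrl 1, -0.659 without shCtrl 2, -0.723 without shTopors 1 and -1.14 without shTopors 2. Apoe, the apolipoprotein E gene, was at 318 ± 153 TPM in shCtrl and 20.3 ± 17.9 TPM in shTopors (SD, n = 2). Alb, the albumin gene, chosen after its values were seen, was at 118 and 271 TPM in shCtrl, 4.15 TPM in shTopors 1 and 402 TPM in shTopors 2, above both controls. Of 19 hepatocyte transcription factor genes, 15 lay below the all-gene median and 3 passed adjusted over the list alone, with a median excess of -0.383 and a camera adjusted p = 0.00143. Foxa1, a pioneer factor of liver development, was at 7.5 ± 1.83 and 1.60 ± 0.0820 TPM. Summed markers of stellate cells, endothelium and leukocytes stood at 309.6 and 270.5 TPM in shCtrl and at 518.9 and 238.9 TPM in shTopors, mostly from Gsn and Fbln2.

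Targets of TGF beta and YAP, interferon-stimulated genes and glucocorticoid targets were lower as sets in camera, while WNT, NF-kB, p53 and NRF2 lists did not pass. Each of the 3 lower lists had an adjusted p = 0.769 with an estimated correlation. The p53 list passed as lower without shTopors 1, with an excess of -0.345, but without shTopors 2 its excess was 0.186. Its mean relative to the control mean was 0.07 in shTopors 1 and -0.628 in shTopors 2. Of 25 TGF beta and YAP targets, 19 lay below the all-gene median and 6 passed adjusted over the list alone, with a median excess of -0.376 and a camera adjusted p = 0.000218. Cyr61, a matricellular protein gene, was at 157 ± 50.6 and 47.4 ± 5.49 TPM. Of 31 interferon-stimulated genes, 26 lay below the all-gene median and 1 passed adjusted over the list alone, with a median excess of -0.361. Ifit1 was at 7.43 ± 0.0897 and 0.515 ± 0.30 TPM. Of 17 glucocorticoid targets, 15 lay below the all-gene median and 1 passed adjusted over the list alone, with a median excess of -0.471. Errfi1, a feedback inhibitor of the EGF receptor, was at 237 ± 95.2 and 60.1 ± 21.8 TPM. The camera adjusted p was 0.00143 for interferon-stimulated genes and 0.0191 for glucocorticoid targets. The interferon call was lost without shTopors 1, where the excess was -0.285. The glucocorticoid call was lost without shCtrl 2, where the excess was -0.358. It was also lost with no filter on low values (camera adjusted p = 0.101), where the excess was -0.444.

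Mitochondrially encoded mRNAs were lower and nuclear-encoded respiratory chain genes higher as sets in camera, and the difference between these lists was not tested. Both lists had an adjusted p = 0.769 with an estimated correlation. All 13 mitochondrially encoded mRNAs lay below the all-gene median, 1 passed over all genes and 7 passed adjusted over the list alone, with a median excess of -0.642 and a camera adjusted p = 3.70e-06. Mitochondrial genes took 1.56% and 1.25% of TPM in shCtrl and 0.72% and 0.82% in shTopors. Of 39 nuclear-encoded respiratory chain genes, 34 lay above the all-gene median, none passed over all genes and only Cox5a passed adjusted over the list alone, with a median excess of 0.356 and a camera adjusted p = 1.34e-05. That excess was 0.2 after quantile normalization and 0.225 with no filter on low values.

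Of 311 genes with Zfp symbols, which encode zinc finger proteins, 258 lay below the all-gene median. None passed adjusted over the list alone. Their median excess was -0.252, with a camera adjusted p = 2.94e-06 and an adjusted p = 0.792 with an estimated correlation. Zfp385b was at 11.3 ± 4.23 TPM in shCtrl and 2.77 ± 0.835 TPM in shTopors. Without shTopors 1 the Zfp list's adjusted p was 0.124 and its excess -0.12, and without shTopors 2 the excess was -0.41. Of 17 imprinted genes, 13 lay below the all-gene median and 4 passed adjusted over the list alone, with a median excess of -0.301 and a camera adjusted p = 0.0191. The imprinted list had an adjusted p = 0.769 with an estimated correlation. Peg3, a paternally expressed gene, was at 772 ± 176 and 313 ± 48.3 TPM. The list's camera call was lost without shTopors 1, where its excess was -0.223, and without shCtrl 1, where its excess was -0.308. With no filter on low values the camera adjusted p was 0.151. Its excess was -0.132 with no filter and -0.166 after a trend on transcript length and GC was removed.

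The remaining lists past the camera threshold had means that overlapped between groups. With an estimated correlation the adjusted p = 0.769 for hypoxia and glycolysis genes and for small nuclear and nucleolar RNAs, and 0.852 for CTCF, cohesin and condensin. Of 29 hypoxia and glycolysis genes, 23 lay above the all-gene median, 1 rose and 1 fell adjusted over the list alone, and the median excess was 0.523 with a camera adjusted p = 0.000189. Ndrg1 went against its list, at 486 ± 106 TPM in shCtrl and 189 ± 54.4 TPM in shTopors. Without shTopors 1 the list's adjusted p was 0.78 and its excess 0.143, and without shTopors 2 the excess was 1.16. The 106 small nuclear and nucleolar RNAs had a median excess of 0.222 and an adjusted p = 0.000188, with Snord60 past the threshold both over all genes and adjusted over the list alone. Without shTopors 2 that list's adjusted p was 0.126, and its excess was 0.358 without shCtrl 2, 0.056 with no filter on low values and 0.131 after the length and GC trend was removed. The 27 genes of CTCF, cohesin and condensin had a median excess of 0.258 and an adjusted p = 0.0077, with none past adjusted over the list alone. That p was 0.186 without shCtrl 1, where their excess was 0.091, which was 0.127 with no filter on low values. Ncapg, a condensin subunit gene that overlaps Lcorl on the other strand, was at 3.09 ± 1.30 and 8.49 ± 1.46 TPM.

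**Figure D2:**
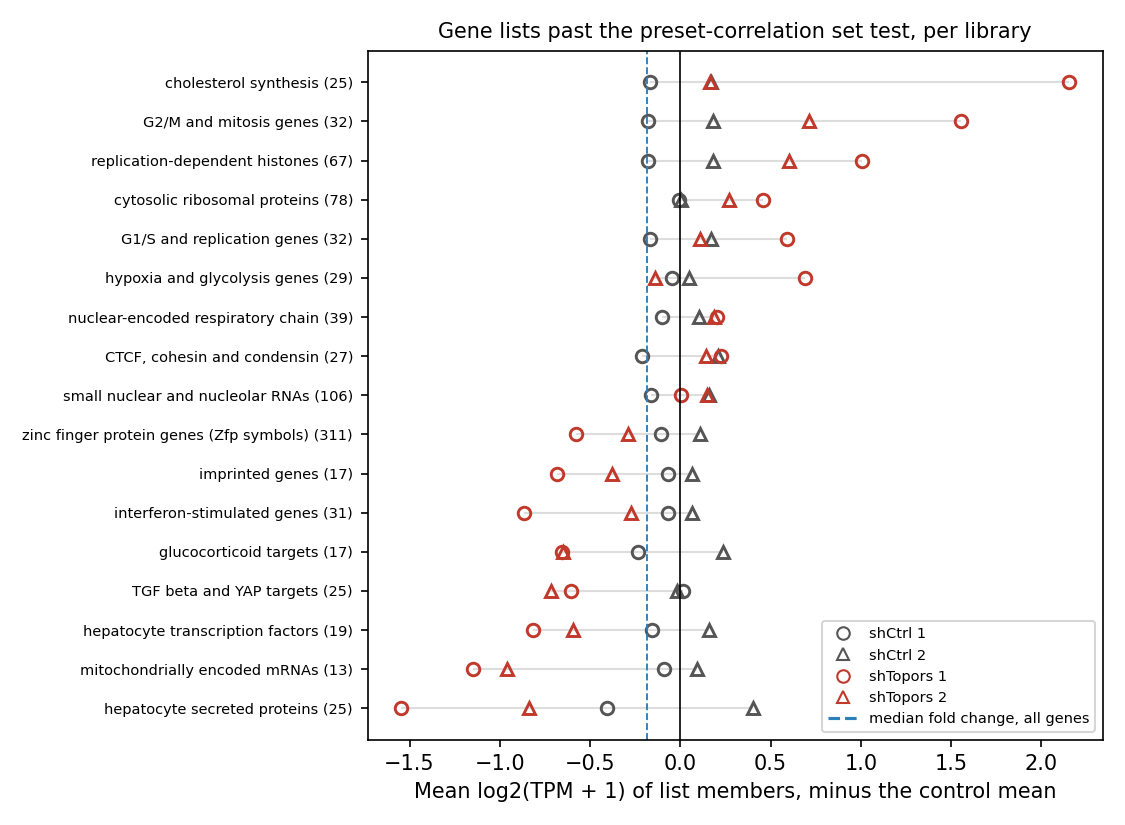
Mean log2(TPM + 1) of the members of each of the 17 lists past the camera threshold, relative to the control mean, in each library, with the number of tested members in brackets. Grey marks are shCtrl, red marks are shTopors, circles are replicate 1, triangles are replicate 2, and the dashed line is the median change of all genes at -0.183. The cholesterol synthesis list stands at 2.15 in shTopors 1 and 0.165 in shTopors 2.

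Camera with its preset correlation called 9 lists higher and 8 lower of 36 tested, and 12 of the 17 had both knockdown libraries on one side of both controls. These means were not corrected for the all-gene median of -0.183. All 8 lower lists lay on one side, but only some of the 9 higher ones did. Many tested lists that did not pass also lay on the lower side. These were the immediate early, SUMO, Polycomb, PML, cadherin, NRF2, collagen, mesenchymal and epithelial junction lists. A position on the lower side is therefore not separate support for the lower calls. With an estimated correlation none passed, and none passed in fry, where the lowest adjusted p was 0.222. The estimated-correlation test rests on 2 residual degrees of freedom, so it could not decide whether correlated members made the calls. TGF beta and YAP targets, with an estimated correlation of -0.021, went from a camera p of 7.28e-05 to 0.0476 before adjustment. Among lists past the camera threshold, only this one had an estimated correlation below the preset value. The estimate was 0.974 for cholesterol synthesis, 0.936 for G2/M, 0.701 for histone, 0.573 for G1/S and 0.258 for Zfp genes. For those lists the loss of the call may come from correlated members, from low power or from both.

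Other lists did not pass in camera. The adjusted p was 0.0525 for immediate early genes, where Dusp1 was at 69.0 ± 45.6 and 19 ± 0.124 TPM, and 0.20 for fatty acid oxidation genes. The immediate early list passed as lower in camera without shCtrl 1 (1.28e-09), shTopors 1 (0.000287) or shTopors 2 (0.0175), with an excess of -0.715, -0.483 and -0.43. It also passed with median-of-ratios scaling (0.0211), quantile normalization (0.012), a pseudocount of 5 (0.0483), a filter at a mean of 5 TPM (0.0311) and the length and GC trend removed (0.0269). Without shCtrl 2 its adjusted p was 0.739 and its excess 0.086. With all libraries the adjusted p was 0.284 for the SUMO pathway, for Polycomb and Trithorax proteins, for heat shock genes and for PML nuclear body components. It was 0.306 for cadherins, 0.320 for unfolded protein and amino acid stress genes, and 0.477 for fatty acid synthesis. It was 0.535 for NF-kB and acute phase genes, for nuclear lamina and heterochromatin proteins and for WNT targets. It was 0.609 for fetal liver and bile duct markers, 0.695 for NRF2 targets, 0.724 for collagens and 0.729 for mesenchymal genes. It was 0.815 for p53 targets and for drug and bile acid metabolism, and 0.871 for epithelial junction genes. Without shTopors 1 the cadherin and unfolded protein lists passed as lower, with adjusted p of 0.0192 and 0.000231. Without shTopors 2 fatty acid oxidation passed as lower (0.0063) and fatty acid synthesis as higher (0.000869). Fatty acid oxidation also passed without shCtrl 1 (0.0117) and after quantile normalization (0.0289), the unfolded protein list after quantile normalization (0.0406) and cadherins without shCtrl 2 (0.0446). Adjusted over the list alone, 2 drug and bile acid metabolism genes were higher and 5 lower, 2 collagens were lower, and 1 fetal liver or bile duct marker was higher and 1 lower. Also adjusted over the list alone, 1 gene was lower in each of the fatty acid oxidation, SUMO, PML, cadherin and nuclear lamina lists, and in the SUMO and PML lists that gene was Topors itself. Among the members of these lists with the smallest p, none past the threshold over all genes, were Ephx1 of drug metabolism at 499 ± 13.4 and 143 ± 23.1 TPM, and Hmga2 of the fetal list at 31.8 ± 7.16 and 172 ± 98.2 TPM. Syne1 of the nuclear envelope was at 66.7 ± 10.5 and 15.9 ± 8.43 TPM. Jarid2, a Polycomb cofactor gene, was at 12.2 ± 0.0469 and 5.22 ± 2.31 TPM.

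Fold changes of neighbouring genes along the chromosomes were weakly correlated. Over 13462 adjacent pairs of tested genes, Pearson's r across genes was 0.122, with a permutation p of 1e-04, the smallest that 10000 shuffles can give. The mean absolute difference between neighbours was 0.535 on the log2 scale and 0.582 after shuffling. Genes are not independent replicates. The same r was 0.116 for the difference between the 2 control libraries and 0.122 for that between the 2 knockdown libraries.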

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

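The number of genes past the threshold was the result that moved most. With no filter on low values 0 genes were higher and 0 lower, against 655 and 2075 at an unadjusted p under 0.05 in limma. A filter at a mean of 5 TPM, median-of-ratios scaling, quantile normalization and rescaling without the most abundant genes each gave 0 higher and 1 lower, as did removing the trend on transcript length and GC, chosen after seeing the data. That removal gave 1210 genes higher at unadjusted p under 0.05, and 939 genes lower at unadjusted p under 0.05. Without using length or GC, median-of-ratios scaling gave 1061 higher and 912 lower at that p, and quantile normalization 1024 and 883. The main setting gave 537 and 1447. Removing the trend also took out each library's general offset from the gene means, as both scalings do. The change in these counts therefore goes with such an offset between libraries and cannot be assigned to length or GC. The cause of the offset was not tested. Leaving out 1 library gave from 0 to 687 genes higher and from 0 to 1479 lower. With 1 library in a group, that library is assumed to vary like the other group. Without shCtrl 1 the counts were 1 and 3.

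The Topors transcript level kept its direction under all alternatives run, from -1.68 with a pseudocount of 5 to -2.47 with 0.1. Leaving out 1 library gave -2.07 to -2.47, with adjusted p from 1.895e-07 to 0.872. Of the 36 lists, 0 passed with camera's estimated correlation and 0 in fry. Other settings called 14 to 20 lists. With a pseudocount of 5 the median excess was 0.301 for G1/S, -0.154 for Zfp, -0.187 for interferon-stimulated and -0.164 for imprinted genes. The NF-kB and acute phase list turned from no call to lower without shTopors 2 (adjusted p = 0.0111) and to higher without shTopors 1 (adjusted p = 0.000115), and leaving out 1 library gave an adjusted p from 0.000115 to 0.8705; the cause was not tested. The neighbour correlation ranged from 0.0888 without genes of one symbol stem to 0.132. The lack of depth in TPM leaves the counting error of low genes unknown.

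The replicate numbers are shared by the groups, but nothing ties them to a batch and there are only 2 pairs. Deviations of same-numbered libraries correlated at 0.199 across genes. The replicate block gave 6 genes higher, 27 lower and 18 lists, and the Topors transcript level was then at -2.27 (adjusted p = 0.0498 in limma). Tgfa, Klb and Mcpt8 (adjusted p = 0.0295), Sprr1a (0.0305), Apoe (0.021) and Cox5a, Hmga2, Ifit1 and Errfi1 (0.0498) then passed, as did the immediate early list (0.0197). The other 2 ways to split the libraries called 1 and 2 genes. Splits of 4 libraries are too few for a share under 0.05.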

Other observations

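Some genes and summed lists that were far apart in the knockdown libraries are given here as values, chosen after they were seen. Fdps, of the cholesterol pathway, was at 30.4 and 43.4 TPM in shCtrl, 339 TPM in shTopors 1 and 66.0 TPM in shTopors 2. Summed hypoxia and glycolysis genes stood at 4737 and 4707 TPM in shCtrl, 10610 TPM in shTopors 1 and 4867 TPM in shTopors 2. Summed NF-kB and acute phase genes stood at 971.7 and 1508 TPM in shCtrl, 663.2 TPM in shTopors 1 and 1822 TPM in shTopors 2. Cd74, a leukocyte marker, was at 0.181 and 1.08 TPM in shCtrl, 0.101 TPM in shTopors 1 and 13.3 TPM in shTopors 2. None of these differences between the knockdown libraries was tested, since each is 1 library.

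The tests of the parts of the one-library question, of other cell types and of the length and GC trend were chosen after the data were seen, the last before its own result. Cell division, histone, ribosomal protein and cholesterol synthesis lists were higher as sets in camera, and after a trend on transcript length and GC was removed, 4 of the 4 kept their call and most of their excess, which argues against such a bias as the whole cause. The earlier test of whether 1 knockdown library decides the lists was left undecided, since 3 of the 4 had means above both controls in both knockdown libraries. Those 3, G2/M, histone and ribosomal protein genes, were then picked by that outcome, and their calls without either knockdown library, kept in 3 of 3, argue only against 1 library as the sole source of the call. Cholesterol synthesis stood at 0.165 in shTopors 2, so shTopors 1 may decide its size. An effect of the knockdown is a hypothesis. None of these calls held in camera with an estimated correlation (adjusted p = 0.769), where 2 residual degrees of freedom left little power. The estimated correlations of these lists were also high, from 0.384 for ribosomal protein genes to 0.974 for cholesterol synthesis.

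Genes for proteins secreted by hepatocytes were lower as a set in camera, a call lost with an estimated correlation (adjusted p = 0.769) and with no filter on low values (0.0747). Fry, which tests members against no change rather than against other genes, gave an adjusted p = 0.389. Summed markers of other cell types were 518.9 and 238.9 TPM in shTopors, but at least 92.3% of that sum came from markers that the control cultures also expressed, so it cannot be told apart from expression by the line itself. The 56 markers with a control mean under 1 TPM summed to 5 and 5.6 TPM in shCtrl and to 4.9 and 18.4 TPM in shTopors, with Cd74 at 13.3 TPM in shTopors 2 and Flt1 at 1.84 and 1.98 TPM, which argues against stellate, endothelial or white blood cells as the whole cause. After the length and GC trend was removed, the list's median difference from all genes was -0.847, so such a bias is argued against too. An effect of the knockdown on these genes is a hypothesis, and a difference in culture state between the groups stays open and untested.

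Fold changes of neighbouring genes correlated. The correlation was 0.105 without overlapping pairs, which argues against shared reads as the whole cause, and rho of fold change with gene density was 0.061, which argues against gene density as the cause of this correlation. For genes with 0 to 5 coding genes in a 1 Mb window centred on them, median log2 change was nonetheless -0.244. It was -0.088 for those with over 40. Between the 2 control libraries the neighbour correlation was 0.116, close to that of the knockdown, so a candidate explanation is that neighbours differ together between any 2 libraries. Without overlapping pairs the control value was 0.142, above the 0.105 of the knockdown. Without neighbours of one symbol stem it was 0.103, against 0.0888 for the knockdown. A part that comes from the knockdown is not shown by these values.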
